A study of Caenorhabditis elegans with 2 samples.

How the data were processed

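The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of TRA-4, a zinc finger protein of the nematode Caenorhabditis elegans. Per the labels, the animals were transgenic worms of strain OP640, which carries TRA-4 with a C-terminal GFP-FLAG tag in an unc-119 mutant background, and chromatin was precipitated with an antibody against GFP. The material was whole early embryos of both sexes, collected by bleaching, and the chromatin was sheared by sonication. The labels give 2 biological replicates of this 1 group and no other condition.

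The files were peak lists. For each of 2 genome builds, ce10 and ce11, the authors deposited a relaxed list of regions for each replicate, a relaxed list called on the pooled replicates, and a final set selected by the irreproducible discovery rate (IDR), a measure of how well regions rank alike in replicates. The relaxed lists hold background as well as enriched regions and were the input to the IDR step, per the descriptions deposited with the files. The same descriptions list a control alignment among the sources of each relaxed list, and that control is not analysed here. The peak caller, the aligner and the IDR cutoff are not given in the sources used here. Each deposited region carries a signal value from the authors' peak caller, whose scale differs between lists. It also carries the −log10 of a q-value and the position of its summit, in the deposited narrowPeak format. How the caller computed the signal value is not given in the sources used here. Read counts and sequencing depth are not given in the sources used here, so the depth behind each signal value is unknown. All counts of regions carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

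The signal value was used to rank regions within a list and never to compare levels between lists. The ce11 lists were used for all coordinates, which are 1-based, and ce11 is the assembly named WBcel235 in the reference annotation. The ce10 lists entered only counts, overlap, correlation and chromosome shares, and no coordinates were converted between builds. Gene starts, types and structures came from the Ensembl release 115 annotation of 46890 genes on 6 nuclear chromosomes, of which 19973 are protein-coding and which fall into 11 types. The amino acid of a tRNA gene came from the RefSeq annotation of the same assembly. A gene was counted as having a peak when an IDR summit lay within 500 bp of its start on either side, so a peak between 2 close starts counts for both genes. The final set holds 394 entries with 393 distinct regions, since 1 region is listed with 2 summits, and each entry was counted.

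The overlap of replicates was measured among the 394 strongest regions of each replicate, as many as the final set holds, with 1 bp as the minimum overlap, and was tested against uniform placement on the same chromosome with an exact Poisson-binomial test (one-sided). The share of peaks near protein-coding starts was tested against uniform placement in the same way (two-sided). The share of peaks on each chromosome was tested against chromosome length with an exact binomial test (two-sided). Gene types, 16 gene lists of at least 5 members and 8 short sequence motifs were each tested with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Odds ratios have 0.5 added to each cell, with 95% intervals on the log scale. Genes of a list were compared with all other protein-coding genes. Motifs were counted within 50 bp of summits and in windows of the same size 1000 bp to each side that overlap no IDR peak. As a description, all 2080 pairs of a 6-base sequence and its reverse complement were ranked by the same comparison. The correlation of signal between replicates was tested with 100000 permutations. Peaks and genes are not independent replicates: these tests describe the deposited list of 1 experiment with 2 replicates, and neighbouring genes can share a peak.

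The designs of the planned tests, the gene lists, the motifs and the rule for naming genes were fixed before the data were examined. Added afterwards were the splits by tRNA, snoRNA and snRNA starts, the GC-matched backgrounds, the 6-base sequences and the comparisons of summit positions. The rule took the protein-coding gene nearest to each of the 15 strongest peaks, every member with a peak of the lists for sex determination, dosage compensation, synMuv B and DREAM, and histone deacetylase and NuRD, the 3 strongest members of every other list, and the gene nearest to the strongest peak of each chromosome. It also took xol-1, tra-4, unc-119, nasp-1 and hda-1 whatever their values. Small RNA genes at these peaks were named from the annotation after their values were seen. The symbols opt-2, daf-21 and hsp-16.11 did not match the annotation and were left out of their lists.

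Alternatives fixed beforehand were the other build, the stronger 197 of the IDR peaks, other overlap rules, windows of 200 and 1000 bp, other backgrounds, and the 394 strongest regions of each replicate alone. For the gene lists, a further one gave each peak only to its nearest protein-coding start, at any distance. Alternatives added later left out peaks near tRNA, snoRNA and snRNA starts, matched the background on GC content, or counted repeated regions once. The tests were themselves tested on simulated data: among 100 sets of 394 random summits, the promoter test passed the threshold in 6, the test of X in 7, the tRNA test in 3, at least 1 motif in 3 and at least 1 gene list in 2. With 10 ribosomal protein genes planted, 1 list was called. With 236 regions planted as shared, 236 were found. With TTSSCGC planted at 40 summits, 1 motif was called. With 118 peaks planted at tRNA starts, 121 were found near them. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.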

Results

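The data list genomic regions enriched by precipitation of tagged TRA-4 from early embryos of Caenorhabditis elegans. TRA-4 is a zinc finger protein related to the human factor PLZF, and it acts in sex determination together with the histone chaperone NASP-1 and the histone deacetylase HDA-1. The animals carried a GFP-FLAG tagged TRA-4, and chromatin from 2 biological replicates of pooled-sex embryos was precipitated with an antibody against GFP. With 1 group there was no comparison between conditions. The questions the design allows are how well the replicates match, which genes and sequences lie at the enriched regions, and whether sex determination genes, the partners of TRA-4 and the X chromosome are among them. The authors' final set, selected by the irreproducible discovery rate (IDR), held 394 peaks in the ce11 build and 373 in ce10. The relaxed list of the pooled replicates held 9660 regions in ce11, of which 535 had a q-value under 0.05. The relaxed lists held 19062 regions for replicate 1 and 13957 for replicate 2. The IDR peaks were the 394 strongest regions of the pooled list by signal, with signal values from 101.6 to 610.9 and a median of 134.7. Their median width was 480 bp, and 96.4% had that width. Sequencing depth is unknown, since no read counts were used here.

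The replicates shared most of their strongest regions. Of the 394 strongest regions of replicate 1, 258 (65.5%, 95% interval 60.6 to 70.2) overlapped 1 of the 394 strongest of replicate 2. Uniform placement gives 1.54 such regions (0.391%), and the log10 of the exact p was -515. The 200 strongest regions of replicate 1 were all found somewhere in the relaxed list of replicate 2. That share was 95.9% for ranks 201 to 394, 80.0% for ranks 395 to 1000 and 28.9% for ranks 10001 to 19062. Each of the 394 IDR peaks overlapped a region in both replicates. Among them, 38 ranked below 1000 in replicate 1 and 9 did so in replicate 2, the lowest at rank 13452 and rank 2768. Signal at the IDR peaks correlated between replicates, with a Spearman's rho of 0.616 and a Pearson's r of 0.705 on the log10 scale. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. This is a correlation across peaks, which are not independent replicates. It was taken over the authors' IDR set, which holds the strongest regions of the pooled list. Without the 2 peaks farthest from the median, r was 0.687. Neighbouring peaks can match 1 region of a replicate, so the 394 peaks gave 377 distinct pairs of regions, over which rho was 0.581 (permutation p = 1e-05).

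**Figure D1:**
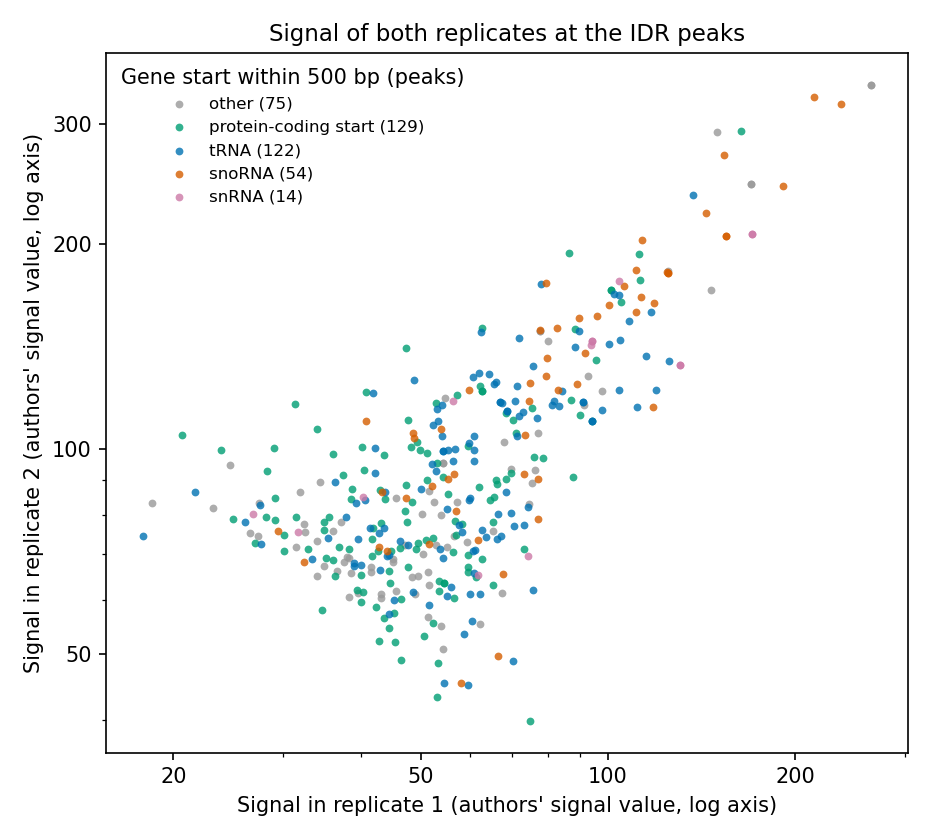
Authors' signal value of each of the 394 IDR peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log axes without units, coloured by the type of gene that starts within 500 bp of the summit. The strongest peak in both replicates, with values of 264.9 and 342.2, lies in the microRNA gene mir-52, and snoRNA peaks are frequent among the strongest.

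Small RNA genes were the most frequent neighbours of TRA-4 peaks. Of 612 tRNA genes, 131 (21.4%, 18.2 to 24.9) had a summit within 500 bp of their start, against 1.02% of all other genes (odds ratio 26.6, 95% interval 21.5 to 32.9, Fisher's exact test, adjusted exact p = 1.24e-119). Among the 346 genes for small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, 54 (15.6%, 11.9 to 19.9) had one, with an odds ratio of 15.7 and an adjusted exact p of 5.20e-41. Genes annotated as small nuclear RNA (snRNA) had 14 of 129 (10.9%, adjusted exact p = 3.09e-09), and microRNA genes had 11 of 261 (4.21%, adjusted exact p = 8.42e-04). The broad class of other noncoding RNA had 182 of 7764 (2.34%, adjusted exact p = 1.69e-16). Some of these genes share their peak with a gene of the types above, for example T03F7.14 with the snoRNA gene T03F7.8 (rank 11). The class was not tested without such genes. Peaks were less frequent at the remaining large types. They lay near 196 of 19973 protein-coding genes (0.981%, adjusted exact p = 7.46e-07), near 3 of 2128 pseudogenes (0.141%, adjusted exact p = 9.02e-09) and near 6 of 15363 piRNA genes (0.0391%, adjusted exact p = 3.17e-92). The other genes in these tests include the tRNA, snoRNA and snRNA genes, and no test left those out. The result for protein-coding genes therefore does not show that peaks avoid them. Counted by peak, 41.9% lay near a protein-coding start, against 18.4% by uniform placement. No summit lay near any of the 20 rRNA genes, which allows a share of up to 16.8%. None of the 9150 other regions of the pooled list lay near one either, so the absence was not particular to the IDR set. The lincRNA and antisense RNA types were not told from other genes, with adjusted exact p of 0.906 and 1.

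Counted by peak, 122 of the 394 (31.0%, 26.4 to 35.8) lay near a tRNA start, where uniform placement gives 0.563% (exact p = 3.39e-174). Another 54 peaks (13.7%) were near a snoRNA start, against 0.338% by uniform placement (exact p = 2.26e-67). The other regions of the pooled list give a background called from the same chromatin. In it 1.95% of regions were near a tRNA start and 0.831% near a snoRNA start, for odds ratios of 22.6 (17.4 to 29.3) and 19.0 (13.2 to 27.3). In all, 190 peaks (48.2%) lay near a tRNA, snoRNA or snRNA start, and 38 of the 50 strongest did. The snoRNA peaks had a median signal of 196.2 in the pooled list, against 146.7 for tRNA peaks, 144.6 for snRNA peaks and 125.9 for peaks at protein-coding starts away from these small RNAs. By median rank in the pooled list the 14 snRNA peaks stood at 168, behind the snoRNA peaks at 81.5. The medians of the regions they matched were 48.5 against 76 in replicate 1 and 58 against 72 in replicate 2. Neighbouring snRNA peaks can match 1 region of a replicate, which counts strong regions more than once. The peaks of ranks 9 and 156 at the snRNA gene sls-2.4 both matched rank 5 in replicate 1 and rank 11 in replicate 2. The replicate medians therefore do not order snRNA against snoRNA peaks. The tRNA and snoRNA shares were also counted in each replicate alone. Among the 394 strongest regions, 27.9% in replicate 1 and 30.2% in replicate 2 were near a tRNA start, and 13.7% and 12.9% were near a snoRNA start. No precipitation of an untagged or unrelated protein was analysed here, so enrichment that any precipitation would give was not subtracted beyond what the authors' caller did.

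**Figure D2:**
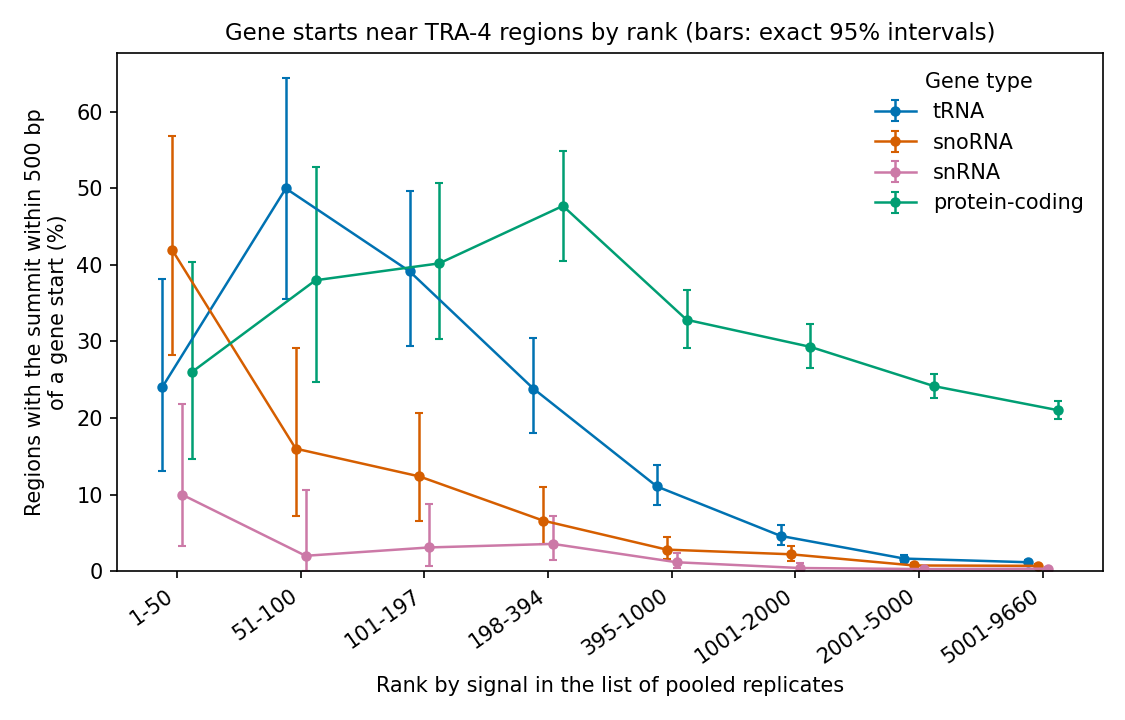
Percentage of regions in the pooled list with the summit within 500 bp of a tRNA, snoRNA, snRNA or protein-coding start (y axis), by rank of the region's signal (x axis, bins of ranks), with exact 95% intervals as bars. The snoRNA share is 42% among the 50 strongest regions and 2.81% at ranks 395 to 1000, and the tRNA share falls from 50% at ranks 51 to 100 to 1.16% at ranks 5001 to 9660.

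Summits took different places at tRNA and snoRNA genes. At tRNA genes the median summit lay 18.5 bp downstream of the start (quartiles 6.25 and 45.75 bp), 113 of 122 were within 100 bp of it, and 87 IDR summits fell inside a tRNA gene. At snoRNA genes the median position was -48 bp (quartiles -66 and -20.25 bp), and 45 of 54 summits (83.3%, 70.7 to 92.1) were upstream. The medians differed by 66.5 bp, with a permutation p of 1e-05, the smallest the permutations can give. The difference was 59.5 bp in replicate 1 and 64 bp in replicate 2, each with the same p.

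**Figure D3:**
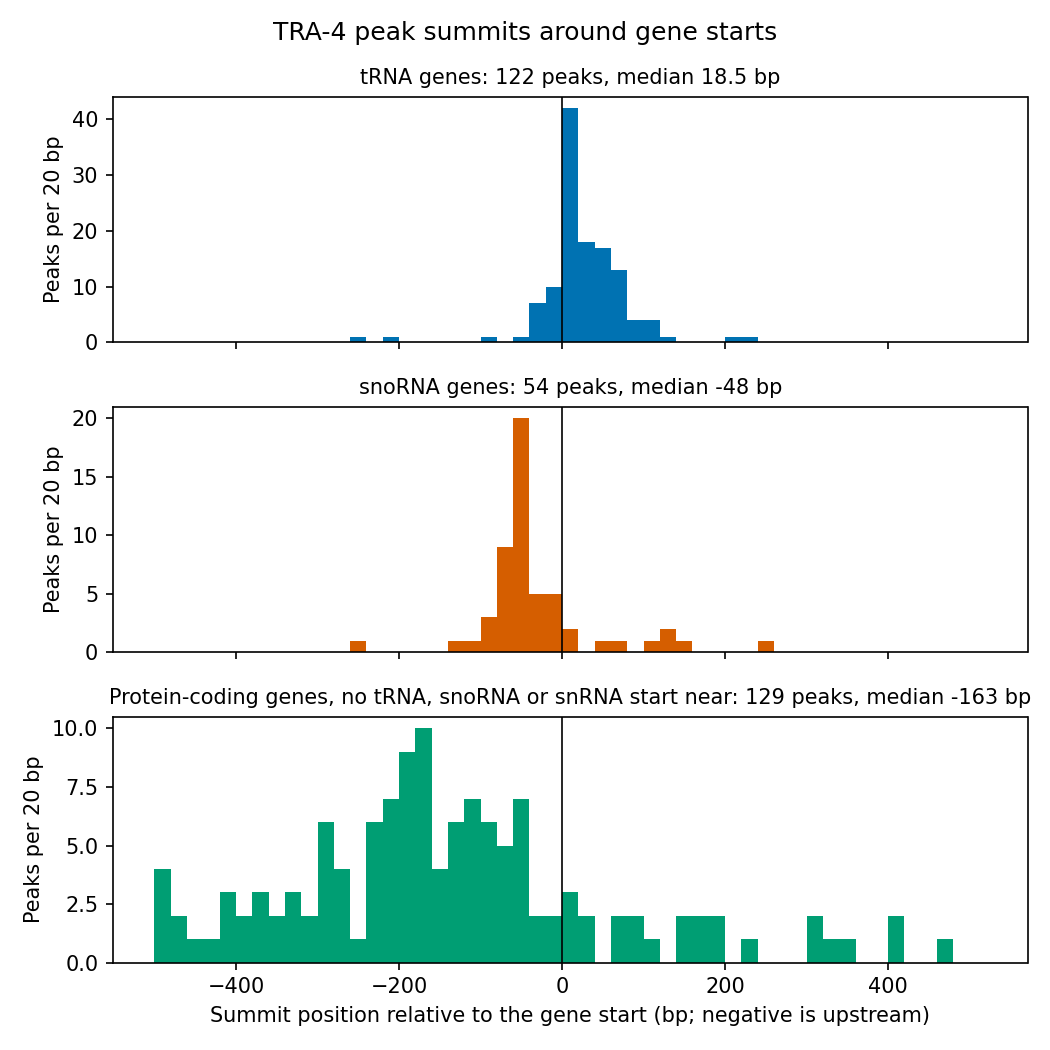
Number of IDR peaks per 20 bp (y axis) by the position of the summit relative to the nearest start of a tRNA gene, a snoRNA gene or, for peaks away from tRNA, snoRNA and snRNA starts, a protein-coding gene (x axis, bp, negative upstream). The 122 tRNA summits centre at 18.5 bp, the 54 snoRNA summits at -48 bp and the 129 protein-coding summits at -163 bp.

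The strongest single peaks were at genes for noncoding RNAs. The strongest of all (chromosome IV, 14033770 to 14034302 in ce11, signal 610.9) had its summit at 14034082 inside the microRNA gene mir-52 (14034008 to 14034107) and ranked 1 in both replicates. The same summit lay inside the noncoding RNA gene Y37A1B.335 (14033942 to 14034090) on the opposite strand. This peak was 9698 bp from the nearest protein-coding start, of Y37A1B.7. The next was on chromosome II (11960697 to 11960976, signal 558.7), with its intergenic summit at -71 bp from the snoRNA gene W03C9.9. The peak at rank 3 (V, 12303494 to 12303753, signal 540.5) had its summit in a snoRNA gene, at the pair C51F7.3 and C51F7.4. Rank 4 (III, 8043871 to 8044099, signal 453.6) was intergenic, at -499 bp from the protein-coding gene K12H4.5. Rank 5 (IV, 11026142 to 11026337, signal 439.5) lay at -106 bp from mir-51, with its summit in the noncoding RNA gene F36H1.17. The nearest protein-coding start there was that of hrg-5, a gene named for its response to heme, 3210 bp away. These 5 peaks ranked between 1 and 10 in each replicate. Of the next 10 peaks, 6 lay at snoRNA genes, among them T06C12.16 near the chemoreceptor gene str-56, ZK265.10 near the chemoreceptor gene sre-23 and D1046.6 inside cfim-2, a gene for a pre-mRNA cleavage factor. The others included sls-2.4, a gene for an SL2 spliced leader RNA, at rank 9 (I, 4172233 to 4172474, nearest protein-coding start egg-5) and a tRNA gene at rank 10 (X, 13665327 to 13665806). The rank 9 summit lay 144 bp from the start of sls-2.4, beyond its end, and at -44 bp from the noncoding RNA gene R12E2.18. Rank 8 was the strongest peak on X (11605795 to 11606072, signal 402.3). Its summit lay inside the noncoding RNA gene F52D10.7 (11605853 to 11605989), and the nearest protein-coding start, at -531 bp, was that of ftt-2, which encodes a 14-3-3 protein. Rank 13 (III, 3499819 to 3500298) was in an intron, at -1002 bp from M01F1.9.

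Peaks away from tRNA, snoRNA and snRNA genes were mostly at promoters. Of all 394 peaks, 165 (41.9%, 37 to 46.9) lay within 500 bp of a protein-coding start, against 18.4% by uniform placement (exact p = 4.81e-27). Among the other regions of the pooled list 23.6% did so (odds ratio 2.34, 1.90 to 2.87, Fisher's exact p = 6.23e-15). Of the 204 peaks away from tRNA, snoRNA and snRNA starts, 129 (63.2%, 56.2 to 69.9) were near a protein-coding start (exact p = 1.62e-44). Among the 190 peaks near those small RNAs 36 (18.9%) were, close to the 18.2% of uniform placement (exact p = 0.835), and the 2 sets differed (Fisher's exact p = 1.48e-19). Of the 129 promoter peaks, 105 (81.4%) were upstream of the nearest start (exact sign test p = 2.80e-13), at a median of -163 bp. By annotation, 182 of the 394 summits (46.2%) lay outside protein-coding and small RNA genes, 21 of them in other noncoding RNA genes and 161 in no annotated gene. Another 70 (17.8%) were intronic, 31 (7.87%) in coding exons, 5 in 5′ UTRs and 8 in 3′ UTRs.

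Of the 16 gene lists tested, histone genes and cytosolic ribosomal protein genes had more peaks than other protein-coding genes. Histone genes had 12 of 50 (24.0%, 13.1 to 38.2) with a summit, against 0.924% of other genes (odds ratio 34.7, 18.1 to 66.8, adjusted exact p = 7.97e-13). The 12 genes were served by 9 peaks, since neighbouring histone genes can share a peak, and no tRNA, snoRNA or snRNA start was near any of them. The strongest (IV, 7487563 to 7488042, signal 189.6) had its summit in the coding exon of his-60, at -446 bp from his-59. Another at rank 154 lay at -250 bp from his-67. The list also held his-24, a linker histone gene, with a peak at rank 204. Core histone genes are near-identical copies, and whether reads shared between copies raise the share of this list was not tested. With replicate 2 left out the list had 7 of 50 (14%, adjusted exact p = 2.13e-06), and among the stronger 197 peaks 4 of 50 (8%, adjusted exact p = 5.07e-04). Ribosomal protein genes had 10 of 76 (13.2%, 6.49 to 22.9), with an odds ratio of 16.7 (8.57 to 32.5) and an adjusted exact p of 2.86e-08. The strongest was rpl-3, with an intergenic summit at -268 bp (III, 3867346 to 3867825, signal 305.1, rank 18). It was followed by rpl-15 at -347 bp (rank 81) and rpl-20 at -286 bp (rank 102). Some of the 10 were weak in replicate 1, where rps-19, rps-22 and rpl-35 ranked 1523, 4198 and 5058. From replicate 1 alone the list had 5 of 76 (6.58%, adjusted exact p = 0.00281), and among the stronger 197 peaks 6 of 76 (7.89%, adjusted exact p = 1.47e-05). Within 200 bp of the start it had 2.63% (adjusted exact p = 0.236), which did not pass the threshold. The heat shock and stress list had 2 of 17 (11.8%, adjusted exact p = 0.0631). These were hsp-1, a cytosolic Hsp70 chaperone gene, at -373 bp (rank 105), and hsp-3, a chaperone gene of the endoplasmic reticulum, at -11 bp (rank 237, but rank 2768 in replicate 2). That list passed the threshold in 4 alternatives, for example from replicate 1 alone (adjusted exact p = 0.0422). It did not pass from replicate 2 alone (5.88%, adjusted exact p = 0.494) or among the stronger 197 peaks (5.88%, adjusted exact p = 0.362). Cuticle collagens had 1 of 156 (0.641%, adjusted exact p = 1), col-85, whose peak also lay near a tRNA gene.

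**Figure D4:**
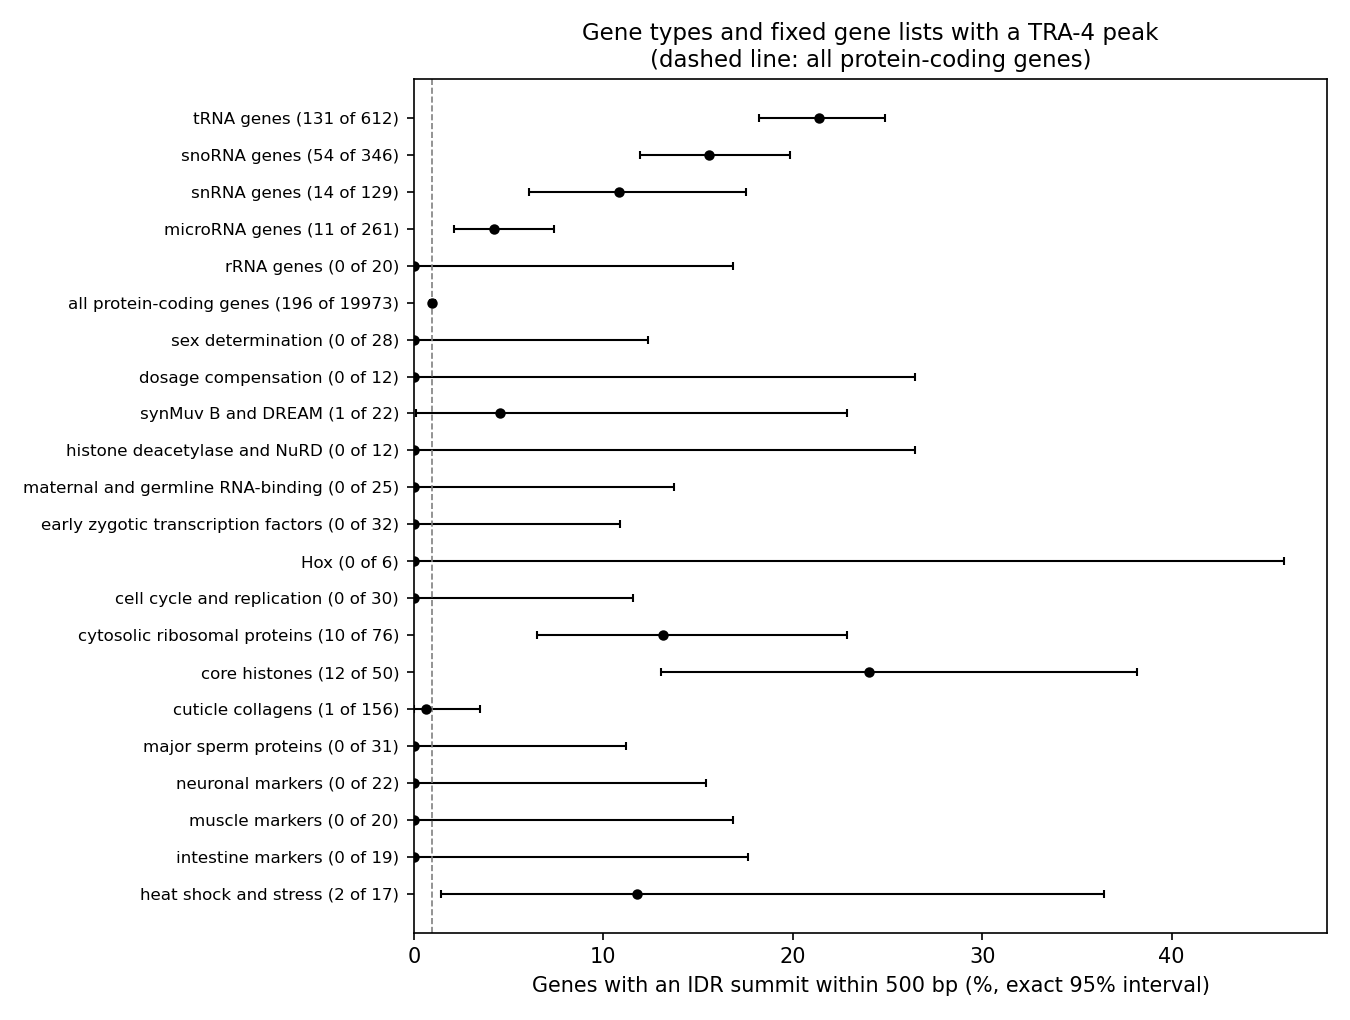
Percentage of genes with an IDR summit within 500 bp of their start (x axis) for gene types and fixed gene lists (y axis), with exact 95% intervals as bars and the share of all protein-coding genes as a dashed line. Histone genes (24.0%), tRNA genes (21.4%), snoRNA genes (15.6%) and ribosomal protein genes (13.2%) lie far above the 0.981% of protein-coding genes.

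Sex determination genes and the partners of TRA-4 had no IDR peak at their starts. None of the 28 sex determination genes had one, which allows a share of up to 12.3%. Neither did any of the 12 dosage compensation genes or the 12 histone deacetylase and NuRD genes, with an upper limit of 26.5% each. The body of the dosage compensation gene mix-1, singled out after its values were seen, held the IDR peak of rank 24 (II, 10839979 to 10840458), in a coding exon and near the snoRNA gene M106.6. Likewise singled out, the IDR peak of rank 172 (III, 2768627 to 2769106) lay beyond the end of the sex determination gene laf-1 (2769356 to 2779053), on the side away from its start. The nearest protein-coding start to that peak was that of swsn-3, at -188 bp. The sex determination switch gene xol-1 (X, 8041313 to 8044409), which promotes male fate, had no region near its start in the pooled list or in either replicate's relaxed list. The same held for nasp-1 and for unc-119, the marker gene of the transgenic strain. For hda-1 no region lay near the start, and the gene body held a weak pooled region at rank 6346 (summit 14526020). At tra-4 itself a region at the start was seen only in replicate 1, at rank 14766, and the gene body held a pooled region at rank 2102 (summit 2855020). In the list of synMuv B and DREAM genes, chromatin regulators that oppose vulval fates, 1 of 22 (4.55%, 0.115 to 22.8, adjusted exact p = 0.781) had an IDR peak. It was lin-35, the worm homologue of the retinoblastoma gene (I, 5807709 to 5815637). Its peak (5807214 to 5807693, signal 157.1) was intergenic, ranked 127 in the set, 111 in replicate 1 and 162 in replicate 2, and lay at -255 bp from lin-35. The nearest start was that of the neighbouring gene vps-51, at -163 bp, so the peak cannot be assigned to lin-35 alone. From either replicate alone the list had 9.09% (adjusted exact p = 0.104 without replicate 1 and 0.0524 without replicate 2).

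No gene of the remaining lists had an IDR peak. These were 25 maternal and germline RNA-binding genes (upper limit 13.7%), 32 early zygotic transcription factor genes (10.9%), 6 Hox genes (45.9%), 30 cell cycle and replication genes (11.6%) and 31 major sperm protein genes (11.2%). Markers of neurons (22 genes, 15.4%), muscle (20 genes, 16.8%) and intestine (19 genes, 17.6%) had none either. Each of these lists, and those for sex determination, dosage compensation and histone deacetylases, had an adjusted exact p of 1. With an expected share of 0.981%, lists of this size could not have shown fewer peaks than other genes.

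The X chromosome held 81 of the 394 peaks (20.6%, 16.7 to 24.9), against 17.7% of the genome's length, a difference that did not pass the threshold (exact p = 0.146, adjusted over chromosomes 0.219). Against protein-coding genes per chromosome (exact p = 1.70e-04) or the other pooled regions (14.3%, Fisher's exact p = 9.92e-04) X held more peaks. The share depended on the kind of peak. Of the 122 tRNA peaks 58 (47.5%, 38.4 to 56.8) were on X, which holds 45.1% of tRNA genes. The share of tRNA genes with a peak was 23.2% on X and 19.9% on autosomes (Fisher's exact p = 0.373). Of the 272 peaks away from tRNA starts, a split made after the data were seen, 23 (8.46%, 5.44 to 12.4) were on X (exact p = 2.18e-05 against length, and 0.0103 against the 13.7% of protein-coding genes on X). With snoRNA and snRNA peaks also left out, 23 of 204 (11.3%, 7.28 to 16) were on X, below the share of length (exact p = 0.0166) but not told from the share of protein-coding genes (exact p = 0.360). None of the 54 snoRNA peaks was on X. Among the autosomes, chromosome III held more peaks than its length gives (18.5% against 13.7%, adjusted exact p = 0.0247) and chromosome V fewer (13.7% against 20.9%, adjusted exact p = 0.00186).

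Of the 8 motifs tested within 50 bp of summits, TTSSCGC, the site of E2F factors, was the most enriched. It was found at 36 of 394 summits (9.14%) and in 2.04% of 784 flanking windows (odds ratio 4.74, 2.62 to 8.60, adjusted exact p = 3.38e-07). The GA repeat GAGAGAGA (2.54% against 0.638%, adjusted exact p = 0.0168) and the GC box GGGCGGG (1.78% against 0.383%, adjusted exact p = 0.0261) were also more frequent at summits. Neither passed the threshold against the summits of other pooled regions (adjusted exact p = 0.0982 and 0.0627). The site of the DREAM subunit LIN-54, TTYGAA, was less frequent at summits than in flanks (18% against 31.4%, adjusted exact p = 1.43e-06). So were its looser form TTYRAA (23.1% against 40.6%, adjusted exact p = 1.63e-08) and the GATA factor site WGATAR (9.90% against 21.4%, adjusted exact p = 1.12e-06). The T-rich motif TTTTTCTT did not differ (2.28% against 3.83%, adjusted exact p = 0.258). TGGGTGGTC, a site of the sex determination factor TRA-1, was found at no summit and in no flank. The interval of its odds ratio ran from 0.0394 to 100, so the test could show neither more nor fewer such sites at summits. Summits were richer in GC than flanks, at 48.0% against 37.3%. TTYGAA, TTYRAA and WGATAR were not tested against summits of the same GC content. Their lower shares at summits therefore cannot be told apart from the difference in GC content. With other pooled summits of the same GC content as background, TTSSCGC stood at 9.14% against 5.20% (odds ratio 1.83, 1.16 to 2.91, Fisher's exact p = 0.0122). It did not pass by this background at the 204 peaks away from tRNA, snoRNA and snRNA starts (10.3% against 6.62%, Fisher's exact p = 0.114) or at the 129 of them near protein-coding starts (7.75% against 5.81%, Fisher's exact p = 0.512). At the other 75 it was found at 14.7% against 6% (odds ratio 2.66, 1.07 to 6.59, Fisher's exact p = 0.0450).

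Among all 6-base sequences, ranked by Fisher's exact p, those leading at tRNA peaks were parts of the conserved internal promoter of tRNA genes. GTTCGA was found at 48.4% of the 122 tRNA summits and in 4.13% of their flanks, and GGTTCG at 45.1% and 2.89%. These peaks were chosen for lying at tRNA genes, so such sequences at them follow from the choice and are no separate finding. At snoRNA peaks the sequence with the lowest p was GGCGCA (24.1% against 0.926%, adjusted exact p = 0.00279). At the 204 peaks away from tRNA, snoRNA and snRNA starts it was GTGCGG, found at 36 summits (17.6%) and in 0.739% of flanks (adjusted exact p = 5.59e-12). There TGCGCG (17.6% against 0.985%) and TGCGGC (16.7% against 0.739%) followed.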

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

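The results below for peaks away from tRNA, snoRNA and snRNA starts, for X away from tRNA starts and for GTGCGG, and the alternatives for them, were tests chosen after the result was seen, as was the counting of repeated regions once. No paired analysis was possible because the study has 1 group. Across 27 results, 157 values were computed under alternatives, 137 of which kept their direction and their side of the threshold or moved little. The replicate overlap ranged from 52.8% to 70.6%, and Spearman's rho was lowest at 0.573. Leaving out a replicate gives no value for the overlap or the correlation, which need both.

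From 1 replicate alone, the lowest and highest values were 34.8% and 39.8% for the promoter share, 19.5% and 20.8% for X, 7.27% and 9.15% for X away from tRNA starts, 19.4% and 21.2% for tRNA genes, and 14.7% and 15% for snoRNA genes. They were 14% and 18% for histones, 6.58% and 13.2% for ribosomal proteins, 2 and 3 gene lists called higher than other genes, 5 and 5 gene types called higher, 7.11% and 10.2% for TTSSCGC, 2 and 3 motifs called more frequent at summits, and 12.5% and 16.6% for GTGCGG.

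The stronger 197 peaks, fewer by construction, gave an X share of 24.9% (exact p = 0.0113), past the threshold. With all peaks the X share of 20.6% also passed it against protein-coding genes (exact p = 1.70e-04) or other pooled regions (exact p = 9.92e-04), both of which put less on X than length does. The low X share away from tRNA starts no longer passed without snoRNA and snRNA peaks and against protein-coding genes (11.3%, exact p = 0.360). Ribosomal proteins had 2.63% within 200 bp (adjusted exact p = 0.236), a narrower window than the -268 to -347 bp of the strongest members. Of the motifs more frequent at summits, 1 was called against other pooled summits in place of 3, a count that leaves out the less frequent ones; the cause was not tested. The synMuv B share of 4.55% was 9.09% from either replicate alone, still short of the threshold, and turned to 0 within 200 bp and with each peak given only to its nearest start, since the lin-35 peak lies at -255 bp and nearer to vps-51. The collagen share passed to the other side of its background in 2 alternatives, far from the threshold in both. With the stronger 197 peaks it stayed at 0.641%, while the share of all protein-coding genes was 0.431%. With nearest starts only it was 3.21%. That alternative set no limit on distance, so peaks farther than 500 bp counted, for example at col-94 (-1982 bp) and col-99 (3922 bp). The same holds for the other lists under that alternative. Depth is unknown, so the absence of a region from the set does not show the absence of binding.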

Other observations

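The tests in this part were chosen after the results were seen, apart from the planned share of ribosomal protein genes with a peak. The genes named here were chosen after their values were seen.

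The tRNA genes with a peak covered nearly all amino acids. Of 21 classes, 20 had a summit at a member, from 10% of 20 histidine genes to 38.5% of 13 cysteine genes, and no class passed the threshold against the other tRNA genes. The lowest p was that of glycine (6 of 55, 10.9%, Fisher's exact p = 0.0569, adjusted 0.988). All 7 annotated genes named mir-51 to mir-56, mir-55b included, lay near a peak. These names cover the mir-51 microRNA family, which is essential in the embryo. The genes were mir-51 and mir-52 at ranks 5 and 1, mir-53 at rank 361, and mir-54, mir-55, mir-55b and mir-56, which share a peak on X (summit 13145112). The gene mir-55b lies within mir-55 on the opposite strand, so the 7 genes are not 7 separate places in the genome. None of the 8 genes of the mir-35 family, also essential in the embryo, had one (upper limit 36.9%). Of the genes for SL2 spliced leader RNA, 5 of 18 had a peak (27.8%, 9.69 to 53.5), and of those for SL1 none of 12 did (upper limit 26.5%). The difference was not tested. The peak counted for sls-2.9 had its summit inside a tRNA gene, at -136 bp from sls-2.9, so it may belong to the tRNA gene. At sls-2.2 and sls-2.8, as at sls-2.4, the summits lay beyond the gene's end, at 157 and 231 bp from the starts of sls-2.2 and sls-2.8. The RNA genes of RNase P and RNase MRP, rpr-1 and mrpr-1, had peaks at ranks 64 and 66, at 72 and 16 bp from their starts. A snoRNA gene inside a protein-coding gene on the same strand had a peak in 23 of 183 cases (13%) and other snoRNA genes more often, by a difference that did not pass the threshold (Fisher's exact p = 0.105).

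In the relaxed pooled list, which holds background too, 9 of 22 synMuv B and DREAM genes had a region at the start (40.9%, against 12.2% of other genes, odds ratio 5.05, 2.2 to 11.6, adjusted exact p = 0.00365). Besides lin-35 these were lin-52 (rank 409, just outside the IDR set), lin-53 (515), lin-54 (547), lin-61 (576), tam-1 (819), ubc-9 (1906), met-2 (6968) and dpl-1 (7545). Several were weak in a replicate, for example lin-53 at rank 13341 in replicate 1. Ribosomal protein genes (42 of 76, 55.3%, adjusted exact p = 3.92e-18) and histone genes (22 of 50, 44.0%, adjusted exact p = 1.84e-07) also exceeded other genes there. Sex determination genes did not (4 of 28, 14.3%, adjusted exact p = 0.948).

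The peaks at tRNA and snoRNA genes could come from reads shared between copies. Of tRNA genes with no identical copy and no copied tRNA gene within 1000 bp, 14.2% (8.32 to 22) had a peak. Only identical sequences counted as copies, so near-identical genes could still share reads and this share cannot exclude them. In regions near tRNA starts a median of 12.2% of 31-base words occurred elsewhere in the genome. A contribution of shared reads stays open, with a peak at 28.3% (21.3 to 36.2) of genes with 2 to 9 identical copies, 21.1% with 10 or more and 14.7% of unique ones. At the 54 snoRNA peaks the share of 31-base words found elsewhere in the genome had a median and an upper quartile of 0%. The highest share was 27.1%. These values argue against exactly repeated sequence as the source of most snoRNA peaks. Near-identical copies were not counted there either, so they are not excluded. Within strata of GC content the odds ratios were 15.3 (11.4 to 20.3) for tRNA and 14 (9.18 to 21.5) for snoRNA genes, lower than the 22.6 and 19.0 before, which argues against GC content as the whole cause. Recovery of highly transcribed or open regions by any precipitation stays open, since ribosomal protein genes also had many peaks (13.2%), and binding by TRA-4 would give the same.

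Few peaks away from tRNA, snoRNA and snRNA starts were on X, which could reflect the content of X. The X share of these peaks was not told from that of protein-coding genes (exact p = 0.360), nor from that of other pooled regions away from those starts (odds ratio 0.797, 0.517 to 1.23). Either explanation, fewer genes or fewer regions called on X, therefore stays open. The absence of snoRNA peaks on X is a separate matter, since 0 of 33 snoRNA genes on X and 54 of 313 on autosomes had a summit (Fisher's exact p = 0.00444), which argues against a mere lack of snoRNA genes there. No biological explanation was tested.

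The sequence GTGCGG at peaks away from tRNA, snoRNA and snRNA starts might follow from their GC content. Against pooled summits matched on GC content it was still more frequent, at 17.6% against 3.43% (odds ratio 5.89, 3.12 to 11.1, Fisher's exact p = 6.48e-09), which argues against GC content as the whole cause. At the 129 of these peaks near protein-coding starts it stood at 23.3%, against 5.04% of GC-matched pooled summits also near such starts (odds ratio 5.57, 2.82 to 11, Fisher's exact p = 4.30e-07), and at the other 75 at 8% against 3.33% (Fisher's exact p = 0.187). TGCGCG also passed against GC-matched summits, at all 204 peaks (odds ratio 3.55) and at the 129 (3.49). At the 75 it stood at 12% against 4% (Fisher's exact p = 0.0429). That p was not adjusted for the sequences and sets tried, so it does not show that the signal extends beyond promoters. GC-rich sequence elements beyond base composition may mark these peaks, as a hypothesis found and tested on the same peaks; contact by TRA-4 was not tested.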
